A study of Mus musculus with 8 samples.

How the data were processed

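Islets of obese and weight-cycled mice, 4 libraries per group, were freed with collagenase and picked by hand, and messenger RNA was enriched on poly-A beads, per the labels' protocols. The deposited values are TPM per gene, made by the authors with Salmon 1.5.2 on build mm10, per the submitters' processing notes. Salmon assigns reads to transcripts by their sequence and scales by transcript length, so reads of near-identical copies (Ins1 and Ins2, trypsins, amylases, Reg genes) are shared by estimate. How transcripts were summed to genes and which annotation was used are not given in the sources used here. Each of the 8 columns summed to between 999930 and 999949 over 35596 genes, so that a gene's TPM falls when others rise, and depth cannot be recovered. Of the gene IDs, 35527 (99.8%) had a symbol in the name table and 69 did not. Transcript lengths and coordinates came from GENCODE M21 on GRCm38, the assembly that mm10 names. The length of a gene was the median over its protein-coding transcripts, or over all its transcripts where none was protein-coding, and 99.95% of tested genes had one.

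The tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes with a mean TPM of at least 1 over all libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend) on log2(TPM + 1), two-sided, with Benjamini-Hochberg adjustment at 0.05 and no covariate. A fold change is on the log2(TPM + 1) scale, weight-cycled minus obese, and understates changes of low genes. Of 36 gene lists, 31 had at least 5 measured members and were tested with camera (preset correlation 0.01), with camera at an estimated correlation, and with fry. Counts of members past the threshold were taken over all genes tested and adjusted over the list alone. Library scores of 11 cell-type lists (mean log2(TPM + 1) over members) and log2 ratios of Gcg, Sst and Ppy to the sum of Ins1 and Ins2 were compared by exact permutation over the 70 assignments of libraries. Principal components were computed on centred log2(TPM + 1).

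Genes were named by rule: the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, leaving out predicted gene models; a fixed set of islet genes (Ins1, Ins2, Iapp, Gcg, Sst, Ppy, Pdx1, Mafa, Nkx6-1, Slc2a2, Ucn3, Glp1r, Abcc8, Kcnj11); and up to 4 members with the smallest p of each list described. Some genes that the rule takes are not reported here. Groups did not overlap for 1817 tested genes (22.4%). The mean over all assignments of the libraries is 2.86%, but genes vary together, so any given assignment can lie far from it and the excess is no test.

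Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at a mean TPM of 5, median-of-ratios and quantile scaling, rescaling without hormone, acinar and mitochondrially encoded genes, robust and untrended variance, array weights, the replicate number as a block, the acinar score as a covariate, a threshold of 0.1, and leaving out each library. Chosen after the data were seen were the removal of trends with transcript length, alone or with GC content (a loess of span 0.5 per library on the deviation from the gene mean), the repeats of the scaled and length-corrected counts without single libraries and with the block, the fit without obese replicate 1 and weight-cycled replicate 2 together, an estimated correlation after scaling and after length correction, a cell cycle score without the filter, a test of the acinar minus the endothelial score, and tests of the beta-cell identity, glucose-sensing and glycolysis members together. Count-based tests were not run, since the values are not counts.

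The limma fit was tested on simulated TPM with the means and residual spreads of these genes and 200 changed genes. With 7967 simulated genes tested, it recovered 39.1% of changes of 0.5, 88.1% of changes of 1 and 100% of changes of 2 on the log2 scale, with 4 unchanged genes called. With a simulated length trend, the length-corrected fit recovered 37.5%, 94.8% and 100% over 8037 genes, with 4 unchanged genes called. Noise was drawn independently for each gene and library, so apart from that trend the simulation lacked variation shared by genes within a library. The numbers of unchanged genes called therefore do not measure false calls in these data.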

Results

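Gene expression was profiled by RNA sequencing of polyadenylated RNA from pancreatic islets, the hormone-secreting cell clusters of the pancreas, of male C57BL/6J mice, an inbred laboratory strain. The 4 obese libraries came from mice fed a 10% fat diet for 9 weeks and then a 60% fat diet for 18 weeks. The 4 weight-cycled libraries came from mice fed the 60% diet for 9 weeks, the 10% diet for 9 weeks and the 60% diet again for 9 weeks. Time on each diet was thus equal and its order differed, and the comparison asks how islet transcripts differ between these orders. The orders also set the last unbroken period on the 60% diet, 18 against 9 weeks. The series has no other group to tell this apart from a period of weight loss and regain. Rises and falls below are relative to obese islets. Values were TPM, a gene's abundance relative to its library's total, which keep no record of sequencing depth, so the depth is unknown and no counting interval is given. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these libraries, which may be technical.

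The metallothionein genes Mt1 and Mt2, Trpm5, Slc2a2 and Mafa were among the lower genes in weight-cycled islets, and Serpina7, Txnip, Ssr4 and Cdk1 among the higher. Mt2 (ENSMUSG00000031762.7, chromosome 8, 94172664 to 94173568, build mm10), a metal-binding protein gene, was at 55.5 ± 6.73 TPM in obese and 16.5 ± 7.11 TPM in weight-cycled islets (SD, n = 4 each), a log2 fold change of -1.76 (SE 0.224, limma adjusted p = 0.0144). Its neighbour Mt1 fell by 1.64 on the log2 scale. Trpm5 (ENSMUSG00000009246.14, chromosome 7, 143069153 to 143094642), a calcium-activated cation channel gene, went from 37.8 ± 3.98 to 13.6 ± 5.69 TPM (limma adjusted p = 0.0165). Slc2a2 (ENSMUSG00000027690.13, chromosome 3, 28697903 to 28731359), the glucose transporter gene of mouse beta cells, went from 73.9 ± 14.1 to 34.3 ± 8.79 TPM, a log2 fold change of -1.10 (SE 0.176, limma adjusted p = 0.0165). Mafa, a transcription factor gene of mature beta cells, fell by 1.10 (SE 0.222). Nnat, Apoe, Gstm1, Atf5 and Chd3 completed the 10 genes with the largest falls among those whose groups did not overlap.

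In the other direction, Serpina7 (ENSMUSG00000031271.14, chromosome X, 139079257 to 139085236), a thyroxine-binding globulin gene, went from 10.3 ± 1.73 to 38.6 ± 20.7 TPM (SD, n = 4), a log2 fold change of 1.66 (SE 0.310, limma adjusted p = 0.0247). Txnip, a thioredoxin inhibitor gene induced by glucose, went to 137 ± 29.7 TPM in weight-cycled islets, a log2 fold change of 1.12 (SE 0.185, limma adjusted p = 0.0184). Ssr4, a gene of the translocon-associated complex, went from 433 ± 48.3 to 839 ± 184 TPM, and Fkbp11, a prolyl isomerase gene of the secretory pathway, from 70.7 ± 14.5 to 159 ± 55.1 TPM. Cdk1, the mitotic kinase gene, rose from 0.295 ± 0.149 to 2.22 ± 0.832 TPM (limma adjusted p = 0.0144), and Cenpa, a centromeric histone gene, from 0.237 ± 0.0849 to 2.33 ± 1.49 TPM. Dapl1, Stmn1, Ttyh1 and Gast also rose. All 10 of these higher genes and 9 of the 10 lower ones also passed the threshold after median-of-ratios scaling and after length correction, the exception being Mafa (limma adjusted p = 0.0611 and 0.0505). On TPM as deposited, 0 of them passed without obese replicate 1 or without the filter on low values. Without weight-cycled replicate 4, 3 of the higher and 2 of the lower passed, while all 10 of each passed without weight-cycled replicate 1 or obese replicate 4.

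**Figure D1:**
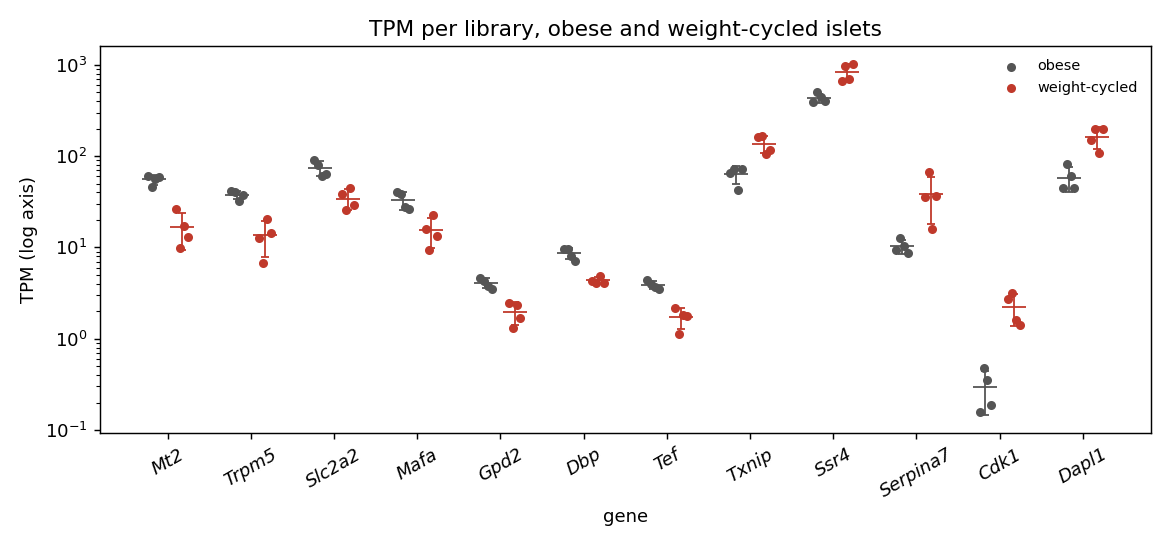
TPM per library on a log axis for 12 genes in obese (grey) and weight-cycled (red) islets, with 4 points per group, a horizontal mark at the mean and bars of 1 SD. Mt2 averaged 55.5 and 16.5 TPM and Cdk1 0.295 and 2.22 TPM in obese and weight-cycled islets, and the groups do not overlap in any of the 12 genes.

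Across the 8127 genes with a mean TPM of at least 1, limma called 98 higher and 1946 lower in weight-cycled islets, 25.2% of those tested. The median log2 fold change of all tested genes was -0.26, and relative to it Mt2 lay at -1.51, Slc2a2 at -0.84, Serpina7 at 1.92 and Txnip at 1.37. Median-of-ratios scaling, which moves that median to -0.01, gave 101 higher and 46 lower genes, and removal of each library's trend with transcript length, chosen after the data were seen, 155 higher and 93 lower. Of the 98 genes called higher on TPM, 54 were also called higher after scaling, 75 after length correction and 53 after both. Of the 1946 lower genes, 39 were called lower in all 3 fits. The scaled total of 147 became 0 without obese replicate 1, 3 or 4 or weight-cycled replicate 4, 13 without obese replicate 2 or weight-cycled replicate 2, 81 without weight-cycled replicate 3 and 3053 without weight-cycled replicate 1. The length-corrected total of 248 became 0 without obese replicate 1 or 4, 51 and 11 without obese replicates 2 and 3, and 2123, 40, 131 and 32 without weight-cycled replicates 1, 2, 3 and 4.

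Insulin transcripts took most of every library, and no difference in their share passed the test. Ins1 and Ins2 together made up 77.4% ± 0.671 of TPM in obese and 77.6% ± 1.51 in weight-cycled islets (SD, n = 4 each; exact permutation test, two-sided, p = 0.914). They are near-identical copies, so the split between them is uncertain. The log2 ratio of Gcg, the glucagon gene, to insulin transcripts was -6.65 ± 0.631 in obese and -7.17 ± 0.879 in weight-cycled islets (SD, n = 4; exact permutation p = 0.371). The ratios of Sst, the somatostatin gene, and Ppy, the pancreatic polypeptide gene, differed by -0.29 and -0.06 (exact permutation p = 0.257 and 0.943), where the smallest p the design allows is 0.0286. Iapp, which encodes a peptide released with insulin, had a log2 fold change of 0.31 (SE 0.158, limma adjusted p = 0.129).

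Genes of beta-cell identity, glucose sensing and glycolysis held many lower members. Of 23 measured identity genes, 14 were lower, 0 higher and 9 did not pass (15 lower when adjusted over the list alone), with a median log2 fold change of -0.51. Pdx1 and Nkx6-1, transcription factor genes, changed by -0.61 (SE 0.178) and -0.64 (SE 0.147), and Ucn3, a peptide gene of mature beta cells, by -0.63 (SE 0.151). Of 20 glucose-sensing genes, 11 were lower, 0 higher and 9 did not pass (16 lower when adjusted over the list alone), among them Kcnj11, the pore of the ATP-sensitive potassium channel, at -0.66 (SE 0.168) and Gpd2, a mitochondrial glycerol phosphate dehydrogenase gene, at -0.80 (SE 0.144). Abcc8, the other subunit of that channel, was at -0.52 (limma adjusted p = 0.0651). Of 16 glycolysis genes, 11 were lower, 0 higher and 5 did not pass (13 lower when adjusted over the list alone), including Gapdh at -0.50 (SE 0.107) and Eno2 at -0.57 (SE 0.123). Camera at a preset correlation placed glucose sensing and glycolysis below other genes (adjusted p = 0.0321 and 0.01), but not with an estimated correlation (adjusted p = 0.948 with an estimated correlation for both). Beta-cell identity did not pass (camera adjusted p = 0.114, and adjusted p = 0.948 with an estimated correlation). After median-of-ratios scaling it passed at the preset correlation (adjusted p = 0.00820) but not with an estimated one (adjusted p = 0.547 with an estimated correlation). The 3 medians were below 0 under each of the 6 scalings and corrections. After median-of-ratios scaling (medians -0.24, -0.28 and -0.16) 2, 3 and 0 members were lower and 1, 0 and 0 higher. The higher member was Pcsk1, a prohormone convertase gene named after its values were seen, at 0.42 after scaling and 0.10 before. Weight-cycled replicate 1 lay nearest to the obese libraries for Nkx6-1, at 29.2 TPM against 16.8 to 22.5 TPM in the others of its group.

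Of 20 exocytosis genes, 11 were lower, 0 higher and 9 did not pass (14 lower when adjusted over the list alone; camera adjusted p = 0.147), including Rph3al at -0.64 (SE 0.135) and Vamp2, a vesicle fusion gene, at -0.64 (SE 0.165). Of 14 islet receptor genes, 5 were lower and 9 did not pass (8 lower when adjusted over the list alone; camera adjusted p = 0.188), namely the incretin receptor genes Glp1r at -0.87 (SE 0.226) and Gipr at -0.46 (SE 0.131), and Ffar1, Sstr3 and Chrm3. Of 11 circadian clock genes, 7 were lower, 0 higher and 4 did not pass (8 lower when adjusted over the list alone; camera adjusted p = 0.0906). Dbp, a clock-driven transcription factor gene, went from 8.63 ± 1.24 to 4.36 ± 0.386 TPM (SD, n = 4; limma adjusted p = 0.0144), and Tef, a related gene, from 3.89 ± 0.383 to 1.73 ± 0.444 TPM. After median-of-ratios scaling, and again after length correction, 0 exocytosis and 0 receptor genes passed, and 3 clock genes were lower and 1 higher. Medians of these 3 lists were below 0 under each scaling. Of 21 antioxidant genes, 8 were lower, 2 higher and 11 did not pass (the same numbers when adjusted over the list alone), with Mt1, Mt2 and Nfe2l2, an antioxidant regulator gene, among the lower and Txnip and Txn1 higher. Their median was -0.28 while camera pointed to higher (adjusted p = 0.211). After median-of-ratios scaling 2 antioxidant genes were lower and 1 higher, and after length correction 2 were lower and 2 higher.

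Of 28 unfolded protein response genes, 3 endoplasmic reticulum genes were higher, Derl3 at 0.92 (SE 0.190), Creld2 at 0.73 (SE 0.162) and Sdf2l1 at 0.69 (SE 0.158), and 3 regulators or targets lower, Atf6, Ddit3 and Asns (3 higher and 0 lower when adjusted over the list alone). The list's median was -0.06 while camera placed it above other genes (adjusted p = 1.16e-05, but adjusted p = 0.804 with an estimated correlation), and the median was 0.26 after median-of-ratios scaling, with 6 higher and 0 lower. Quantile scaling put that median at 0.005, and rescaling without hormone, acinar and mitochondrial genes at -0.05. Of 18 granule and prohormone-processing genes, 3 were higher, Sec11c at 0.85 (SE 0.149), Tmed6 and Scg5, and 3 lower, Slc30a8, the granule zinc transporter gene, at -0.61 (SE 0.132), Ptprn2 and Pcsk1n, with the same numbers when adjusted over the list alone. Here too the median, -0.11, and camera, higher, differed in sign (adjusted p = 0.000611, but adjusted p = 0.948 with an estimated correlation), and the median was 0.22 after median-of-ratios scaling. That scaling gave 4 higher and 0 lower granule genes, and length correction 5 higher and 0 lower. The granule median stayed at -0.09 both with quantile scaling and with hormone, acinar and mitochondrial genes left out. Of 76 cytosolic ribosomal protein genes, 3 were higher, Rplp0, Rpl12 and Rpl27, and 73 did not pass (0 called when adjusted over the list alone), with a median of 0.13 (camera adjusted p = 3.15e-29, but adjusted p = 0.6 with an estimated correlation). After median-of-ratios scaling 0 ribosomal genes passed, and after length correction 1 was higher and 0 lower. Of 37 nuclear oxidative phosphorylation genes, Ndufa1 was higher, Sdha, Atp5b, Atp5d and Cox5a were lower and 32 did not pass (1 higher and 1 lower when adjusted over the list alone). Their median was 0.01, their mean -0.02 and camera's direction higher (adjusted p = 4.95e-05, but adjusted p = 0.948 with an estimated correlation), and Atp5b and Atp5d turned to 0.05 and 0.02 after median-of-ratios scaling. That scaling left 0 of these genes called, and length correction 1 higher and 0 lower. Of 7 dedifferentiation and progenitor genes, Serpina7 and Gast, the gastrin gene, were higher and 5 did not pass, also when adjusted over the list alone (camera adjusted p = 4.44e-05, but adjusted p = 0.569 with an estimated correlation), and Aldh1a3 was at 0.48 (limma adjusted p = 0.153). Fev, also among those that did not pass, went the other way, at -0.66 to -0.16 over the alternatives, and passed in 3 of 21. Of 10 cell cycle genes, Cdk1 and Tyms, a thymidylate synthase gene, were higher and Cdk4 and Ccnd2, regulators of cycle entry, lower, also when adjusted over the list alone. Their median was -0.04, or 0.16 after median-of-ratios scaling, and their mean 0.06 (camera higher, adjusted p = 0.00663, but adjusted p = 0.569 with an estimated correlation). After that scaling, as after length correction, 1 cell cycle gene was higher and 0 lower. Fry, which tests whether a list moves one way on balance, called 0 of 31 lists (11 at an unadjusted p under 0.05). Chrm3, Txn1, Ddit3, Asns, Ptprn2, Pcsk1n and Cox5a were named after their values were seen.

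**Figure D2:**
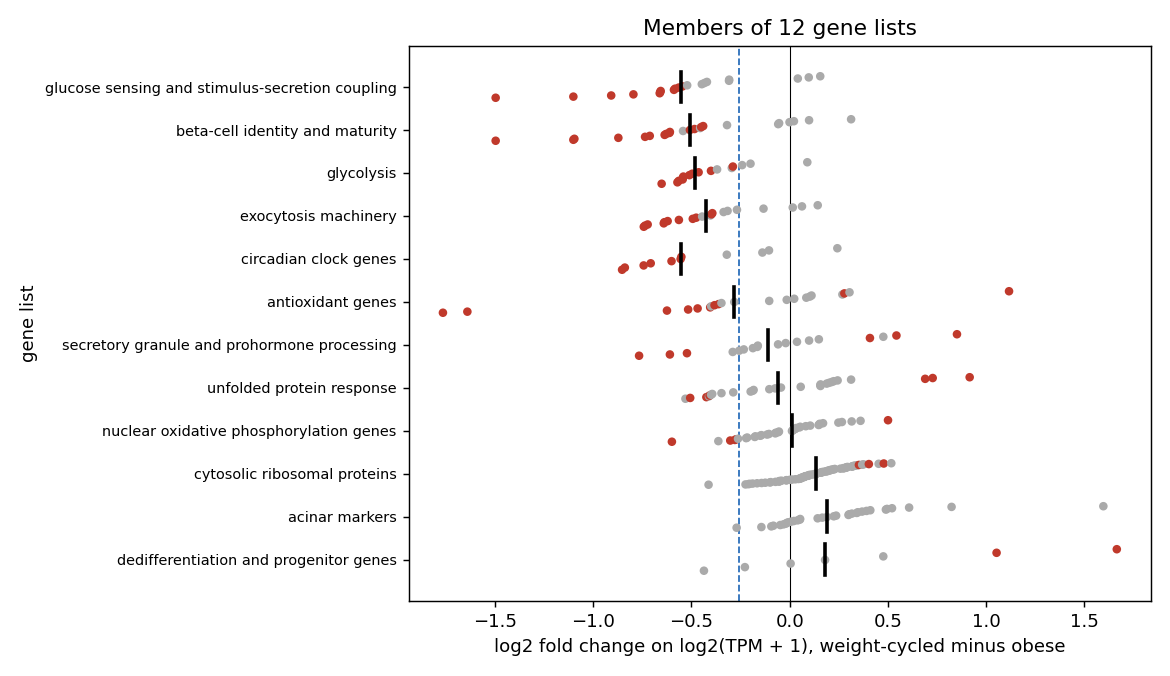
Log2 fold change on the log2(TPM + 1) scale, weight-cycled minus obese, of each measured member of 12 gene lists, with members past the limma threshold in red and others in grey, each list's median as a black bar, 0 as a solid line and the all-gene median of -0.26 as a dashed line. Glucose sensing (median -0.56) lies left of the dashed line and ribosomal proteins (median 0.13) right of it, while the medians of granule genes (-0.11) and the unfolded protein response (-0.06) turn to 0.22 and 0.26 after median-of-ratios scaling.

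Markers of other cell types were measured beside these groups. None of the 11 cell-type scores passed the exact permutation test, the smallest p being 0.0857 for macrophage, adipocyte and nerve markers (0.251 adjusted over the 11 scores). The acinar score was 5.72 ± 0.318 in obese and 5.95 ± 0.585 in weight-cycled islets (SD, n = 4; exact permutation p = 0.6). None of 33 acinar genes passed the threshold, also when adjusted over the list alone, while camera placed the list above other genes (adjusted p = 5.81e-15, but adjusted p = 0.804 with an estimated correlation). Acinar transcripts took 1.18% of TPM in weight-cycled replicate 1 and at most 0.736% in any other library, and trypsin, amylase and Reg genes are near-identical copies whose single values are uncertain. Of 11 alpha-cell markers, Ttr and Gc were higher and Slc7a2 lower, also when adjusted over the list alone. Of 9 macrophage markers, Lyz2, Ctss and Tyrobp were lower, also when adjusted over the list alone, and the list's median of -0.24 turned to 0.03 after median-of-ratios scaling. After that scaling, as after length correction, 0 macrophage markers passed, and 1 alpha-cell marker was higher and 0 lower.

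The first principal component held 66.8% of the variance, and obese libraries scored from -23.3 to -5.03. Weight-cycled replicate 1 scored -7.98, among the obese libraries, and the other weight-cycled libraries 13.8 to 30.6. A gene's deviation from its mean rose with transcript length in the obese libraries (Spearman's rho 0.184 to 0.375, across genes, which are not independent replicates) and in weight-cycled replicate 1 (0.345), and fell with it in the other weight-cycled libraries (-0.400 to -0.283). Over 5 equal bins of genes by length, the median fold change went from -0.14 in the shortest to -0.36 in the longest.

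**Figure D3:**
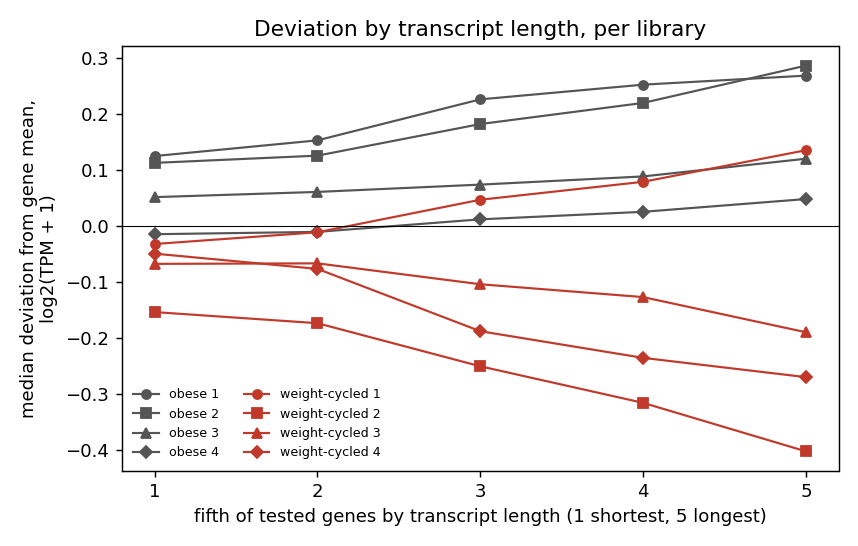
Median deviation from the gene mean on the log2(TPM + 1) scale against transcript length, in 5 equal bins of the tested genes, with 1 line per library, obese in grey and weight-cycled in red. The line of weight-cycled replicate 1 climbs from -0.03 to 0.14, as those of the obese libraries climb, and that of weight-cycled replicate 2 falls from -0.15 to -0.40.

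The total of 2044 genes called by limma became 0 without obese replicate 1 (2670 at an unadjusted p under 0.05), and 37, 34 and 1728 without obese replicates 2, 3 and 4. It became 39, 71 and 10 without weight-cycled replicates 2, 3 and 4, and 4660 without weight-cycled replicate 1. Without the filter on low values limma called 0 of 19482 genes (5686 at an unadjusted p under 0.05, smallest adjusted p = 0.0912), so each adjusted p above holds for all 8 libraries and the 8127 genes tested.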

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

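The tests of hormone share, of library scaling, of cell mixture and of transcript length for the beta-cell lists were chosen after the result each concerns was seen, and intervals come from resampling genes, not libraries. A library far from the other 3 of its group was sought by Dixon's ratio in 208 groups of reported values, and 9 passed where chance gives 10.4. Acinar transcripts took 1.18% of TPM in weight-cycled replicate 1 against 0.507% to 0.588% in the others of its group, and the correlation of its deviations with transcript length was 0.345 against -0.400 to -0.283. The log2 ratio of Gcg to insulin was -8.48 in weight-cycled replicate 2 against -6.90 to -6.61. Ins2 was at 652871 TPM in weight-cycled replicate 4 against 685775 to 688724 TPM. Obese replicate 2 stood above its group for Tmed6 (20.8 TPM against 16.1 to 16.9), Scg5 (560.01 against 473 to 487) and Ndufa1 (289 against 249.6 to 254). Reg2 was at 15.5 TPM in obese replicate 1 against 1.48 to 1.87, and Atf5 at 28.7 TPM in obese replicate 3 against 35.8 to 37.2.

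Most tested genes had lower TPM in weight-cycled islets. A larger share of hormone, acinar and mitochondrial transcripts is argued against, since with these left out the median log2 fold change was -0.31 (95% bootstrap interval -0.32 to -0.30). Chance cannot be excluded for the number of genes called: 2 of the 35 splits of the libraries gave at least 2044, and the split exchanging obese replicate 4 for weight-cycled replicate 1 gave 3378, which points to a structure of the samples that crosses the groups. A preference for short transcripts in some libraries stays open, since rho of fold change against length was -0.37 across genes while the shortest genes also lay below 0, at -0.14 (interval -0.16 to -0.12), between the bounds set for either outcome. For the 147 genes after median-of-ratios scaling and the 248 after length correction, 1 of 35 splits, the real one, gave as many. The highest other split gave 1 in each case. This argues against chance but cannot exclude it, since 1 of 35 is the smallest share the design allows. Both totals also became 0 without obese replicate 1 and without obese replicate 4, and the first also without obese replicate 3 or weight-cycled replicate 4. The length correction was chosen after the data were seen.

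Beta-cell identity, glucose-sensing and glycolysis transcripts held many lower members. Library scaling and transcript length stay open as causes, since the median over all 56 measured members, -0.50 (interval -0.55 to -0.44) on TPM, was -0.21 (interval -0.27 to -0.14) after median-of-ratios scaling and lay at a residual of -0.24 (interval -0.32 to -0.18) from the length trend, and both intervals reach across the bound set for excluding either. The difference in library means of these members passed after each correction (exact permutation p = 0.0286, the smallest possible), but not without obese replicate 1 or 2 after scaling or any 1 obese replicate after length correction (0.0571), nor for identity alone after scaling (0.0571, or 0.0857 without obese replicate 1, 2 or 4 or weight-cycled replicate 2), and the 3 lists passed camera at its preset correlation (adjusted p = 0.00820, 0.00294 and 0.0239 after scaling, and 0.00245, 0.00118 and 0.000594 after length correction) but not with an estimated correlation (adjusted p = 0.547, 0.501 and 0.501, and 0.643, 0.543 and 0.543), while 3 and 5 of the 33 called members still passed, as their median fold change went from -0.59 (median SE 0.151) to -0.31 (0.110) and -0.35 (0.0999). Fewer beta cells among other cell types stays open. Acinar and endothelial markers moved apart by 0.54 (interval 0.36 to 0.77), and over libraries by 0.59 (exact permutation p = 0.0286, the smallest possible, but 0.0857 without weight-cycled replicate 1 and 0.0571 without obese replicate 1 or 3, a test added later). This argues only against a like rise of both marker sets. It cannot decide the question, since acinar tissue carried along with hand-picked islets can vary apart from the share of beta cells. The order of the diets may account for some lower members and stays an untested hypothesis, since it also sets the last unbroken period on the 60% diet, 18 against 9 weeks, and a group given the 60% diet for its last 9 weeks alone would be needed to tell these apart.

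Clock output genes were lower as well. Transcript length as the whole cause stays open. The median residual of Dbp, Tef, Nr1d1, Nr1d2, Per1 and Bhlhe41 from the length trend was -0.42 (interval -0.61 to -0.22). These 6 were all among the genes called lower, so their residual cannot decide the question. Dbp, Tef and Nr1d2 alone of the 6 passed after length correction (limma adjusted p = 0.0164, 0.0164 and 0.0384). The 11 measured clock genes, a list fixed beforehand, had a median of -0.23 after that correction, with 3 lower and 1 higher. Another phase of the clock at collection and the diets' order stay open: Arntl, which peaks opposite to Dbp, lay 0.23 above the all-gene median, within its SE of 0.265, and Npas2 at -0.18 (SE 0.344), both under 1 TPM, and the labels give no time of collection.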

How the results depend on the processing

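The length corrections, the fit without 2 libraries and the repeats of the scaled and length-corrected totals were chosen after the data were seen. The total of 2044 genes (98 higher, 1946 lower) stayed within 1.5 times with pseudocounts of 0.1 and 5, robust variance and no variance trend. It was 0 (0 higher, 0 lower) without the filter, where more genes are tested, 1080 (1001 lower) with the filter at 5, 147 (46 lower) with median-of-ratios and 297 (173 higher, 124 lower) with quantile scaling, 919 (821 lower) after leaving out hormone, acinar and mitochondrial genes, 4795 (296 higher, 4499 lower) with array weights, 4470 (258 higher, 4212 lower) with the acinar covariate, 3963 (210 higher, 3753 lower) at a threshold of 0.1, 248 (155 higher, 93 lower) after length correction, 275 (139 lower) after length and GC correction, and 0 (0 and 0, with 1570 at an unadjusted limma p under 0.05) without obese replicate 1 and weight-cycled replicate 2. Leaving out each library gave 0 to 4660 genes (0 to 270 higher, 0 to 4390 lower), 0 to 3053 after median-of-ratios scaling (0 to 1609 higher, 0 to 1444 lower) and 0 to 2123 after length correction (0 to 1093 higher, 0 to 1030 lower). The total of 0 came without obese replicate 1 in each case, after scaling also without obese replicate 3 or 4 or weight-cycled replicate 4, and after length correction also without obese replicate 4. The highest total came without weight-cycled replicate 1 in each case. The cause was not tested. Without depth, no counting error can be given for low genes.

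Whether replicate numbers pair the libraries is unknown, since the labels do not say. Deviations of same-numbered libraries correlated at 0.210, -0.276, -0.0522 and 0.231, which cannot decide it with 4 libraries per group. With the replicate block the total was 2903 (149 higher), 449 after median-of-ratios scaling (357 higher, 92 lower) and 401 after length correction (267 higher, 134 lower), and beta-cell identity passed camera (adjusted p = 0.0397).

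Of 31 lists, 9 passed camera, 0 with an estimated correlation and 0 with fry. Without the filter 13 of them passed, or 14 of the 36 testable there. With the filter at 5 it was 6 of the 22 testable, and 8 to 13 passed under the others that kept the preset correlation. These are adjusted p. Without the filter beta-cell identity (0.0152), exocytosis (0.00373), interferon (0.0178), clock (0.00522) and insulin signalling genes (0.0101) passed and oxidative phosphorylation (0.0648) did not. With the filter at 5 glucose sensing did not pass (0.117) and the cell cycle turned to lower (0.785). With median-of-ratios scaling beta-cell identity (0.00820) and the clock (0.00610) passed. With quantile scaling beta-cell identity (0.000214), exocytosis (0.0202), mitochondrially encoded (0.0131) and clock genes (0.0364) passed, and granule (0.827), unfolded protein (0.245), oxidative phosphorylation (0.419), cell cycle (0.0776) and ribosomal genes (0.753) did not. With hormone, acinar and mitochondrial genes left out beta-cell identity passed (0.00955). With array weights mitochondrially encoded (0.00455), cholesterol (0.000172) and immediate early genes (0.00313) passed. After length correction beta-cell identity (0.00245), exocytosis (0.0354) and the clock (0.0495) passed and the cell cycle did not (0.0727). With GC as well beta-cell identity (0.00518), exocytosis (0.0388) and mitochondrially encoded genes (0.0294) passed and the cell cycle did not (0.0544). With an estimated correlation glucose sensing, granule, oxidative phosphorylation and glycolysis were at 0.948, progenitor and cell cycle genes at 0.569, unfolded protein and acinar genes at 0.804 and ribosomal genes at 0.6004. An estimated correlation combined with scaling or length correction, added after the data were seen, left 0 lists. With median-of-ratios scaling it gave 0.501 for glucose sensing, granule, progenitor, unfolded protein, glycolysis and cell cycle, 0.675 for oxidative phosphorylation, 0.636 for acinar and 0.627 for ribosomal genes. With length correction it gave 0.543 for glucose sensing, unfolded protein and glycolysis, 0.643 for granule, progenitor and ribosomal, 0.867 for oxidative phosphorylation, 0.595 for cell cycle and 0.821 for acinar genes. Fry gave 0.104 for glucose sensing, 0.303 for progenitor, 0.0936 for glycolysis, 0.739 for cell cycle, 0.684 for acinar and 0.36 for ribosomal genes, and turned granule (0.969), unfolded protein (0.973) and oxidative phosphorylation genes (0.699) to lower. Leaving out each library gave 0.0171 to 0.165 for beta-cell identity, 3.16e-05 to 0.0697 for granule, 0.0276 to 0.513 for alpha-cell, 0.00813 to 0.998 for cholesterol, 0.00180 to 0.262 for cell cycle, 0.00967 to 0.994 for interferon, 0.0136 to 0.252 for duct, 0.0411 to 0.998 for macrophage and 0.0345 to 0.998 for immediate early genes. The cause was not tested.

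Of the cell-type scores 0 passed, 1 with a pseudocount of 0.1, 1 with median-of-ratios scaling, where duct markers turned to 0.27, and 0 to 3 over left-out libraries, highest without weight-cycled replicate 1. Atp5b and Atp5d turned to 0.0505 and 0.0218 with median-of-ratios scaling. Hormone ratios stayed on their side of the threshold under each alternative run, and the Ppy difference, past it in none, went from -0.39 to 0.28 over left-out libraries.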

Other observations

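Members of the cell cycle list went both ways. Of its 35 genes, 25 had a mean under 1 TPM, and mean TPM was higher in weight-cycled islets for 28, while limma called none of them over the unfiltered table, where it called 0 of 19482 genes (5686 at an unadjusted p under 0.05). Birc5, a mitotic survival gene, was at 0.0740 ± 0.0409 and 0.719 ± 0.325 TPM, and Ccnb1, a mitotic cyclin gene, at 0.0506 ± 0.0339 and 0.630 ± 0.285 TPM in obese and weight-cycled islets (SD, n = 4). Mki67, a proliferation marker, was at 0.0154 ± 0.00699 and 0.0639 ± 0.0659 TPM. The more abundant Ccnd2, Cdk4, Ccnd1 and Ccnd3, genes of cycle entry, had lower means, from 29.7, 28.3, 12.03 and 9.001 TPM in obese to 20.1, 20.6, 10.5 and 7.54 TPM in weight-cycled islets. These genes were picked after their values were seen. Over the members above the filter the mean log2(TPM + 1) differed by 0.06 (exact permutation p = 0.257). A mean of log2(TPM + 0.1) over all 35 genes was -0.97 ± 0.023 in obese and -0.22 ± 0.324 in weight-cycled islets (SD, n = 4), a score chosen because the low members had higher values, so that it is no test of them.

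In other lists all called members were lower, as were 1946 of the 2044 called among all genes (25.2% of those tested), and none of these lists passed camera at its preset correlation. Among lipid genes, 5 of 20 in fatty acid oxidation (Hadh, Hadha, Hadhb, Acadl and Cpt2), 2 of 15 in fatty acid synthesis (Acly and Mlxipl) and 2 of 22 in cholesterol synthesis (Srebf2 among them) were lower, or 11, 2 and 2 when adjusted over the list alone. Of 14 insulin and mTOR signalling genes Akt1 and Akt2 were lower, of 10 senescence genes Igfbp3, Bmi1 and Trp53, of 12 interferon and MHC class I genes Irf1 and Psmb9, of 11 hypoxia genes Vegfa, Ndrg1, Egln1 and Mif, of 12 heat shock genes Hspd1, Hsp90aa1 and Hsp90ab1, and of 10 immediate early genes Btg2. Adjusted over the list alone, the lower counts of these 6 lists were 2, 6, 2, 4, 2 and 0, with 1 hypoxia gene higher. Of 12 endothelial markers Kdr and Esam and of 9 duct markers Krt7 and Epcam were lower (0 and 2 when adjusted over the list alone). The 13 mitochondrially encoded genes had a median log2 fold change of -0.55, and 0 of them, 0 of 8 delta-cell and PP-cell, 0 of 5 stromal and 0 of 5 erythrocyte markers passed, also when adjusted over the list alone. In lists too short to test, 3 of 4 adipocyte genes (Lpl, Pnpla2 and Pparg), 1 of 2 lymphocyte genes (Cd79a), 1 of 3 inflammatory genes (Nfkbia) and 0 of 4 disallowed genes were lower, or 3, 1, 3 and 0 when adjusted over the list alone. After median-of-ratios scaling 0 members of the lists of this paragraph were lower and 1 hypoxia gene was higher. After length correction 1 signalling, 2 senescence and 1 interferon gene were lower, and 0 in the others. The genes of this paragraph were named after their values were seen, and medians of the fatty acid synthesis, cholesterol, interferon, hypoxia, heat shock, immediate early, signalling, duct, stromal, erythrocyte, delta-cell and disallowed lists changed sign between scalings.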
